A study of Mus musculus with 22 samples.

How the data were processed

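RNA was sequenced in bulk from whole ovaries of CD1 mice, an outbred stock, at 11 ages with 2 libraries each, 22 libraries in all. The ages were embryonic days 13, 15 and 17 (E13, E15, E17), the day of birth (P0), postnatal days 3, 7, 14, 21 and 60 (P3, P7, P14, P21, P60), 1 year (Y1) and 2 years (Y2). Each library was placed in its age group by its own label. The labels give no cycle stage or reproductive state, so in adults neither can be told apart from age. The protocol text names P5, which no library has, and omits Y1, and the E15 titles carry the codes 2 and 3, so whether a library was left out is not known here. The fetal columns are printed with fewer decimals than the postnatal ones. Whether both were quantified in the same run is not known here, which bears on every value compared between fetal and postnatal ages. The labels do not say whether the 2 libraries of an age came from separate animals or pools, so the p-values measure only the spread between these samples, which may be technical.

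The values are FPKM (fragments assigned to a gene, scaled by transcript length and by the library's mapped fragments), as deposited in 1 table of 34745 genes by Ensembl gene ID. Per the submitters' processing notes, HISAT2, StringTie and edgeR were used and the genome build was mm10. The series' own design text names TopHat as the aligner, and which of the 2 aligners produced the deposited FPKM is not settled by these sources. Tool versions, the annotation release and the handling of reads that align to several places are not given in the sources used here. FPKM are scaled within a library, so a large rise in a few abundant transcripts lowers the values of all others in that library. Genes whose sequence is nearly repeated elsewhere in the genome depend on how such reads were divided.

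No read counts were used. The depth was estimated from the deposited FPKM: in genes with a single annotated transcript, values under 0.2 FPKM fell on whole multiples of what 1 read is worth at that gene's length. In each library 1643 to 1939 such values were checked up to 5 reads, and 94.2% to 96.2% of them were whole within 0.02 reads. This gave 11510000 to 18180000 reads per library. At that depth 1 FPKM of a transcript of 2 kb stands for 23.0 to 36.4 reads, and lower values rest on correspondingly fewer. A count test was not run, because most genes have several transcripts and their reads could not be recovered from FPKM.

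Genes with at least 1 FPKM in at least 2 libraries were kept, 16117 of 34745. Differences were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with age as a factor of 11 levels in 1 fit to all libraries, which left 11 residual degrees of freedom. The fit shares 1 estimate of the spread of each gene between ages. P-values were adjusted by the Benjamini-Hochberg method within each comparison and called at 0.05. All fold changes are differences on the log2(FPKM + 1) scale, which understates the change of genes near or under 1 FPKM. The results drawn from the fit were an F test over all ages, 4 main comparisons (E17 against E13, P7 against E17, P60 against P7, Y2 against P60), the 10 steps between neighbouring ages, and tests of gene lists. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

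There were 29 gene lists of 522 members in all, covering germ cell stages, somatic cell types of the ovary, immune cells, metabolism and stress, and other tissues that a dissected ovary could carry. They were written from textbook knowledge, and 28 had measured members. The list of Y-linked genes had none at 1 FPKM in at least 2 libraries. Each list was tested in the 4 main comparisons with limma's camera, which compares the members with all other genes, at a preset inter-gene correlation of 0.01 and adjusted over the 28 lists. Camera was repeated with the correlation estimated from the data, and 8 of the 47 list calls held. Each list had the same estimate in all 4 comparisons, so differences between replicates of ages outside a comparison may enter it. The growing oocyte list had an estimate of 0.71. Its mean differed between replicates by 1.16 at Y2, against 0.06 at E17 and 0.18 at P7. How far such differences account for the lost calls was not tested. Counts of members past the threshold are given over all genes tested and adjusted over the list alone.

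The rule for named genes took, in each main comparison, the 5 largest increases and 5 largest decreases past the threshold whose libraries did not overlap and whose higher mean was at least 10 FPKM, leaving out clone names. It added the 3 members with the largest change of each list assigned to that comparison, and for each step the 2 largest increases and 2 largest decreases. Of the genes that the rule took, 2 are not reported here. Other genes are given for their values only. The design, the lists, this rule and most alternative settings were fixed before the data were examined. Gene positions are from GRCm38 with the GENCODE M21 annotation, the assembly that mm10 denotes. Of the gene IDs, 34267 were in the reference name table and 27 gene names that a spreadsheet had turned into dates were restored through their IDs. To show where reads may be shared with a copy, the share of a gene's words of 31 bases found in transcripts of other genes was computed, and copies missing from the annotation were not searched.

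The steps were tested on simulated data with 200 changed genes. Each gene had 1 mean apart from those changes, and the same count dispersion, 0.02, at every age. Real replicates at Y2 had an SD of 0.423, against 0.149 to 0.241 at the other ages, and far more genes changed. The rates for Y2 against P60 therefore do not carry over to these data. The real p-values of that comparison rest on a spread shared with the other ages. The simulation also gave every gene the same dispersion, so the rates of the other comparisons may not carry over either. A 4-fold rise was recovered in 100% of simulated genes in all 4 comparisons, and a fall to 0.25 in 96% to 100%. A rise of 2-fold was recovered in 90% for E17 against E13, 76% for P7 against E17, 66% for P60 against P7 and 76% for Y2 against P60, and of 1.5-fold in 10% to 26%. False calls were 2.1% to 9.2% of the simulated calls, among 14655 to 14691 genes tested. Alternatives tried were no low-value filter, a filter at 5 FPKM, a pseudocount of 0.1, median-of-ratios and quantile scaling, no intensity trend, a replicate block, only the 2 compared ages in the fit, and leaving out each library in turn. Library quality weights and fits without the ages in doubt were added later.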

Results

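Whole ovaries of CD1 mice were profiled by RNA sequencing at 11 ages, from E13, when female germ cells enter meiosis, to animals of 2 years, with 2 libraries per age. Values are FPKM, each mean is given with its SD over n = 2 libraries, and fold changes are on the log2(FPKM + 1) scale, with the later age minus the earlier. The libraries held an estimated 11510000 to 18180000 reads, and 12656 to 13566 genes reached 1 FPKM in each. Across the 11 ages, 14194 of 16117 tested genes changed (88.1%, limma F test with Benjamini-Hochberg adjustment), 8502 of them over a range of at least 1 on the log2 scale and 1117 over at least 3. The mean was highest at E15 for 2224 genes, at E13 for 2039 and at Y2 for 1875, against 495 for P7.

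The replicates of an age resembled each other more than any other library, with Pearson r across genes of 0.98 to 0.992 at 10 ages and 0.94 at Y2. The SD between replicates over genes was 0.149 to 0.241 at the 10 other ages and 0.423 at Y2. Genes with a 4-fold difference between replicates on the FPKM + 1 scale, the higher at 10 FPKM or more, numbered 170 at Y2 and 4 to 38 at the other ages. The mitochondrial genes took 15.4% to 24.7% of the FPKM total, with 23.9% to 24.7% at Y1 and Y2. Among them mt-Atp6 was at 4300 and 719 FPKM in the P3 libraries and at 792 and 5310 at P14. It has 99.5% of its words in other transcripts, so these shares are uncertain. The first 3 principal components held 44.1%, 18.8% and 9.5% of the variance. Whole ovaries were sequenced in bulk, so a change in the share of a cell type cannot be told from a change within its cells. This holds for every gene and list below.

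From E13 to E17 genes of undifferentiated germ cells fell, and most piRNA pathway genes and oocyte transcription factors rose, while meiotic prophase genes went both ways. Of the 7 list calls in this comparison 1, that of the germ cell and pluripotency list, was kept with an estimated correlation. Stra8, the retinoic acid target that starts meiosis (ENSMUSG00000029848, chromosome 6, 34920163 to 34939344), fell from 39.9 ± 2.78 to 0.0751 ± 0.0232 FPKM, a log2 change of -5.25 (limma, adjusted p = 3.66e-11). Sohlh1, a germ cell bHLH factor needed for early folliculogenesis (ENSMUSG00000059625, chromosome 2, 25842995 to 25847248), rose from 1.28 ± 0.00342 to 85.5 ± 21 FPKM, a log2 change of 5.22 (limma, adjusted p = 2.66e-09). In all, 2990 genes were higher at E17 and 2283 lower, of which 760 and 459 differed by at least 1 on the log2 scale.

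Of 20 measured genes of primordial germ cells and pluripotency, 18 fell, 1 rose and 1 did not pass, and the counts adjusted over the list alone were the same 18 and 1. Pou5f1 fell from 20.2 ± 0.152 to 0.406 ± 0.0486 FPKM (log2 -3.92). Lin28a fell from 16.5 ± 1.38 to 0.255 ± 0.268 (log2 -3.81) and Sox2 from 12.8 ± 0.318 to 0.112 ± 0.158 (log2 -3.64), and all are factors of the pluripotent state. This list was lower as a whole (camera, adjusted p = 3.52e-17), and the call was kept with adjusted p = 0.00546 with an estimated correlation. Hmga2, a chromatin protein of proliferating fetal cells, fell from 90.4 ± 1.69 to 4.76 ± 0.294 FPKM (log2 -3.99).

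Meiotic prophase genes split: 17 of 32 rose, 8 fell and 7 did not pass, with 18 and 9 adjusted over the list alone. Sycp1, a transverse filament protein of the synaptonemal complex, rose from 11.1 ± 0.35 to 84.6 ± 0.535 FPKM (log2 2.83). Syce3, of its central element, rose from 3.78 ± 0.238 to 29.6 ± 1.03 (log2 2.68). The list was higher (camera, adjusted p = 0.00285; adjusted p = 0.246 with an estimated correlation). Of 15 genes of the piRNA pathway, which silences transposons in germ cells, 12 rose and none fell, also adjusted over the list alone (camera, adjusted p = 8.75e-09; adjusted p = 0.178 with an estimated correlation). Tdrd9 rose from 1.62 ± 0.281 to 55.1 ± 4.61 FPKM (log2 4.42). Tdrd1 rose from 2.65 ± 0.169 to 31.5 ± 2.14 (log2 3.15) and Piwil2 from 10.7 ± 0.314 to 54.8 ± 6.32 (log2 2.25). Of 11 oocyte transcription factors 8 rose and 1 fell, with 9 and 2 adjusted over the list alone (camera, adjusted p = 8.13e-05; adjusted p = 0.178 with an estimated correlation). Beside Sohlh1, Nobox rose from 0.0489 ± 0.00492 to 21.6 ± 4.36 FPKM (log2 4.42) and Figla from 3.45 ± 0.302 to 80.6 ± 18.1 (log2 4.18).

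From E13 to E17 pre-granulosa and fetal somatic genes rose in 9 of 16 cases and none fell, with 11 higher adjusted over the list alone (camera, adjusted p = 0.00172; adjusted p = 0.422 with an estimated correlation). Foxl2, the granulosa lineage factor, rose from 10.5 ± 0.691 to 59.3 ± 12.1 FPKM (log2 2.38). Gng13 rose from 12.5 ± 1.08 to 70.3 ± 10.9 (log2 2.39) and the cell cycle inhibitor Cdkn1b from 13.4 ± 2.33 to 50.9 ± 11.5 (log2 1.84). The granulosa cell list was also higher, with 10 of 20 members up and 1 down, or 13 and 1 adjusted over the list alone (camera, adjusted p = 0.00015; adjusted p = 0.178 with an estimated correlation). Mitotic cell cycle genes fell, 15 of 26 with none higher and 17 adjusted over the list alone (camera, adjusted p = 1.47e-06; adjusted p = 0.422 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell from 54.9 ± 0.561 to 25.4 ± 7.66 FPKM (log2 -1.11). Mcm7 fell from 28.1 ± 1.25 to 15 ± 1.43 (log2 -0.87) and the spindle checkpoint kinase Bub1 from 31.9 ± 0.356 to 17.4 ± 0.652 (log2 -0.84). Mcm7 has 24.4% of its words in other transcripts and is uncertain, and its call was lost without E13 replicate 1 or E17 replicate 1, at adjusted p of 0.0596 and 0.0708.

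Blood transcripts moved in the same interval. The embryonic globins Hbb-y (836 ± 10.4 to 2.06 ± 0.7 FPKM, log2 -8.11), Hba-x (88.1 ± 1.46 to 0.72 ± 0.208, log2 -5.70) and Hbb-bh1 (22.4 ± 3.04 to 0.438 ± 0.619, log2 -4.09) fell. The red cell gene Hemgn (0.0285 ± 0.0403 to 45.1 ± 42.0, log2 5.10) rose. Of 13 erythroid genes 10 rose and 3 fell, also adjusted over the list alone, and camera did not call the list (adjusted p = 0.561). The E17 libraries differed in erythroid transcripts, with list means of 4.66 and 5.93. Hba-a2, an adult alpha globin, was listed at 0 in both E13 libraries and at 90.1 and 167 FPKM at E17, but 92.6% of its sequence words occur in other transcripts, so its level is uncertain. The same holds for Rpl29 (1.33 ± 0.0489 to 71.3 ± 6.91 FPKM, log2 4.95), with 44.9% of words elsewhere. The counts of higher and lower genes came to 1981 without E13 replicate 1 and 1459 without E13 replicate 2, and 56.7% of calls were higher on the deposited scale against 46.3% after quantile normalization.

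Between E13 and E17 camera did not call the following lists. Endothelial genes were lower in 5 of 14 cases and higher in 1 (camera, adjusted p = 0.0743), and oviduct and mesonephric duct genes lower in 5 of 12 and higher in 2 (camera, adjusted p = 0.0743). Of 31 growing oocyte genes 4 rose and none fell (camera, adjusted p = 0.292). All 3 lists kept these counts adjusted over the list alone. The cumulus, ovulation and luteal list had 1 of 14 members higher and 3 lower, with a median of 0.19 and a mean of 0.11 where camera pointed down (adjusted p = 0.789).

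**Figure D1:**
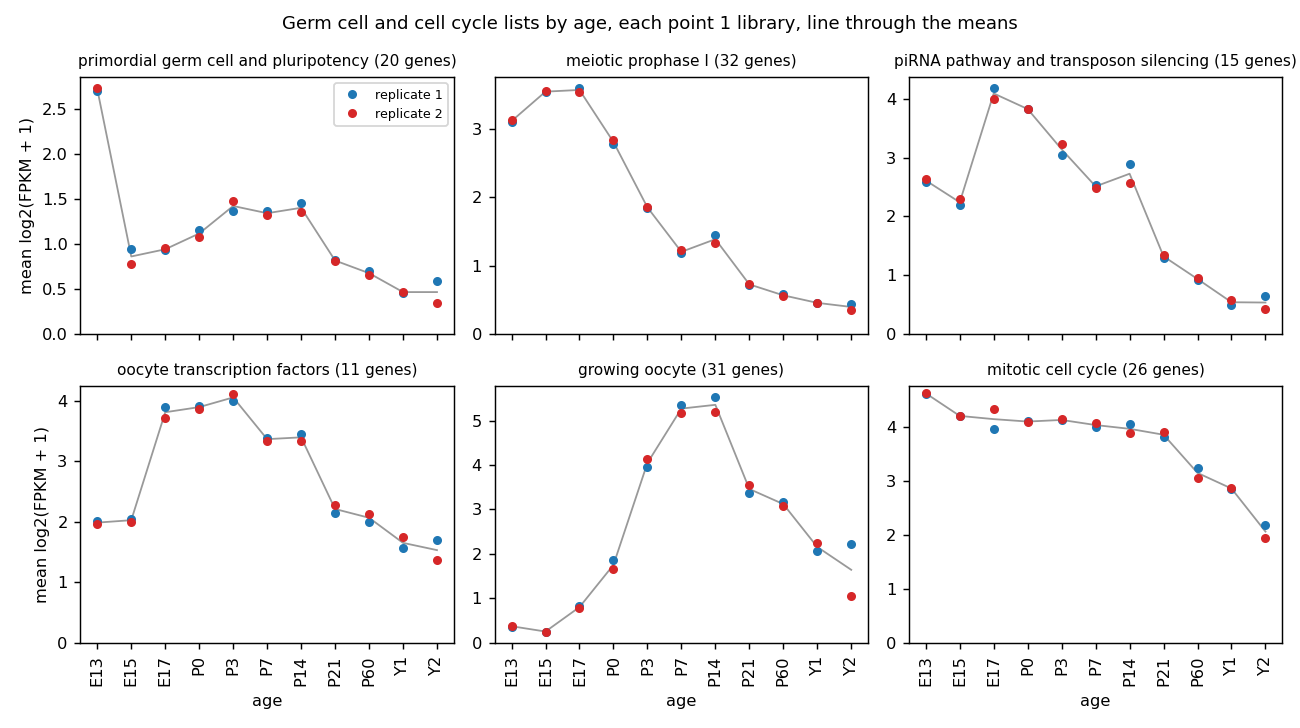
Mean log2(FPKM + 1) of 6 germ cell and cell cycle lists (vertical axes) at each of the 11 ages (horizontal axes), with 1 point per library, blue for replicate 1 and red for replicate 2, and a line through the means. The growing oocyte list lies at 2.22 and 1.06 in the Y2 libraries.

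Between E17 and P7 most meiotic genes fell, and most genes of the growing oocyte, granulosa and steroidogenesis rose. Of the 12 list calls in this comparison 3, those of the meiotic, granulosa and theca lists, were kept with an estimated correlation. The call of the growing oocyte list was lost. Its estimate, 0.71, was the same in every comparison, and the replicates of this list differed most at Y2. Zp3, a protein of the egg coat (ENSMUSG00000004948, chromosome 5, 135980099 to 135988624), rose from 0.3 ± 0.0406 to 342 ± 0.397 FPKM, a log2 change of 8.05 (limma, adjusted p = 1.92e-09). Taf7l, a germ cell paralogue of a TFIID subunit (ENSMUSG00000009596, chromosome X, 134460118 to 134476490), fell from 134 ± 10.1 to 0.125 ± 0.109 FPKM, a log2 change of -6.91 (limma, adjusted p = 1.28e-15). In all, 2683 genes were higher at P7 and 3329 lower, 969 and 775 of them by at least 1 on the log2 scale. Higher genes made up 44.6% of these calls on the deposited scale and 50.2% under median-of-ratios scaling.

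Of 31 growing oocyte genes 30 rose and none fell, also adjusted over the list alone, with a mean log2 change of 4.47 (camera, adjusted p = 1.8e-30; adjusted p = 0.11 with an estimated correlation). Padi6, a component of oocyte cytoplasmic lattices, rose from 1.39 ± 0.195 to 522 ± 27.4 FPKM (log2 7.77) and Nlrp14 from 0.273 ± 0.0479 to 265 ± 2.61 (log2 7.71). Gdf9, the oocyte growth factor that acts on granulosa cells, rose from 0.542 ± 0.558 to 175 ± 17.3 (log2 6.88). Khdc1b rose from 0.595 and 0.206 FPKM in the E17 libraries to 218 and 205 at P7 (log2 7.26). Of 32 meiotic prophase genes 30 fell and none rose, also adjusted over the list alone (camera, adjusted p = 7.76e-27), and the call was kept with adjusted p = 3.89e-04 with an estimated correlation. Sycp1 fell from 84.6 ± 0.535 to 1.22 ± 0.0945 FPKM (log2 -5.27) and Hormad1, of the chromosome axis, from 42.5 ± 3.34 to 0.669 ± 0.236 (log2 -4.71). Hormad1 has 36.3% of its words in other transcripts and is uncertain. Syce3 was listed at 0 in both P7 libraries against 30.3 and 28.9 FPKM at E17. Tktl1 fell from 51.7 ± 3.16 to 0.158 ± 0.0377 FPKM (log2 -5.51).

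The piRNA list reversed its fetal rise, with 12 of 15 members lower and 2 higher, also adjusted over the list alone (camera, adjusted p = 2.4e-07; adjusted p = 0.172 with an estimated correlation). Oocyte transcription factors went both ways, with 3 of 11 higher and 6 lower, also adjusted over the list alone (camera, adjusted p = 0.23). Sohlh1 fell from 85.5 ± 21 to 17 ± 0.437 FPKM (log2 -2.25) and its partner Sohlh2 from 14.1 ± 1.74 to 1.96 ± 0.0553 (log2 -2.35). Tbpl2, the oocyte's TATA-binding protein paralogue, rose from 0.267 ± 0.0559 to 5.35 ± 0.927 (log2 2.32).

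Granulosa genes rose, 13 of 20 with 1 lower, or 14 and 1 adjusted over the list alone (camera, adjusted p = 6.03e-09; adjusted p = 0.0164 with an estimated correlation). Amh, the hormone of small growing follicles, rose from 1.4 ± 0.346 to 133 ± 23.1 FPKM (log2 5.80). Hsd17b1 rose from 0.921 ± 0.492 to 58.0 ± 9.26 (log2 4.96) and Inha, the inhibin alpha subunit, from 43.2 ± 6.24 to 878 ± 67.1 (log2 4.32). Of 17 theca and steroidogenesis genes 15 rose and none fell, also adjusted over the list alone (camera, adjusted p = 8.54e-09; adjusted p = 0.008 with an estimated correlation). Cyp11a1, which starts steroid synthesis from cholesterol, rose from 0.295 ± 0.0102 to 46.8 ± 4.37 FPKM (log2 5.20). Cyp17a1, needed for androgens, rose from 1.8 ± 1.0 to 84.0 ± 8.4 (log2 4.97) and Hsd3b1 from 13.7 ± 11.2 to 577 ± 12.5 (log2 5.54). Pre-granulosa genes fell, 9 of 16 with 2 higher, also adjusted over the list alone (camera, adjusted p = 0.00632; adjusted p = 0.414 with an estimated correlation). Gng13 fell from 70.3 ± 10.9 to 2.69 ± 0.287 FPKM (log2 -4.27). Lgr5 fell from 12.7 ± 0.522 to 1.18 ± 0.22 (log2 -2.65) and the WNT agonist Rspo1 from 45.3 ± 6.25 to 10.4 ± 1.28 (log2 -2.02).

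Of 22 collagen and matrix genes 9 rose and none fell, also adjusted over the list alone (camera, adjusted p = 0.00991; adjusted p = 0.426 with an estimated correlation). Fbn1 rose from 15.9 ± 1.64 to 43.1 ± 1.82 FPKM (log2 1.39). Dcn rose from 158 ± 13 to 382 ± 26.7 (log2 1.27) and Lum from 72.7 ± 1.11 to 152 ± 0.389 (log2 1.05). Other tissues moved as well. Of 13 erythroid genes 12 fell, or 13 adjusted over the list alone (camera, adjusted p = 1.49e-06; adjusted p = 0.241 with an estimated correlation), among them Slc4a1 (97.6 ± 91.4 to 0.176 ± 0.148 FPKM, log2 -5.99) and Hba-a2 (129 ± 54.7 to 1.48 ± 2.01, log2 -5.93). Of 12 adipocyte genes 8 rose and 1 fell, or 10 and 1 adjusted over the list alone (camera, adjusted p = 0.00999; adjusted p = 0.598 with an estimated correlation). Of 13 smooth muscle and pericyte genes 11 rose and none fell, with 12 adjusted over the list alone (camera, adjusted p = 3.77e-07; adjusted p = 0.151 with an estimated correlation).

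Complement and antigen presentation genes rose in 12 of 18 cases between E17 and P7, or 13 adjusted over the list alone (camera, adjusted p = 1.49e-06; adjusted p = 0.172 with an estimated correlation). Endothelial genes rose in 5 of 14, also adjusted over the list alone (camera, adjusted p = 0.00503; adjusted p = 0.374 with an estimated correlation). Surface epithelium genes fell in 6 of 13, also adjusted over the list alone (camera, adjusted p = 0.109). Macrophage genes did not move as a group, with 2 of 20 lower (camera, adjusted p = 0.954).

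**Figure D2:**
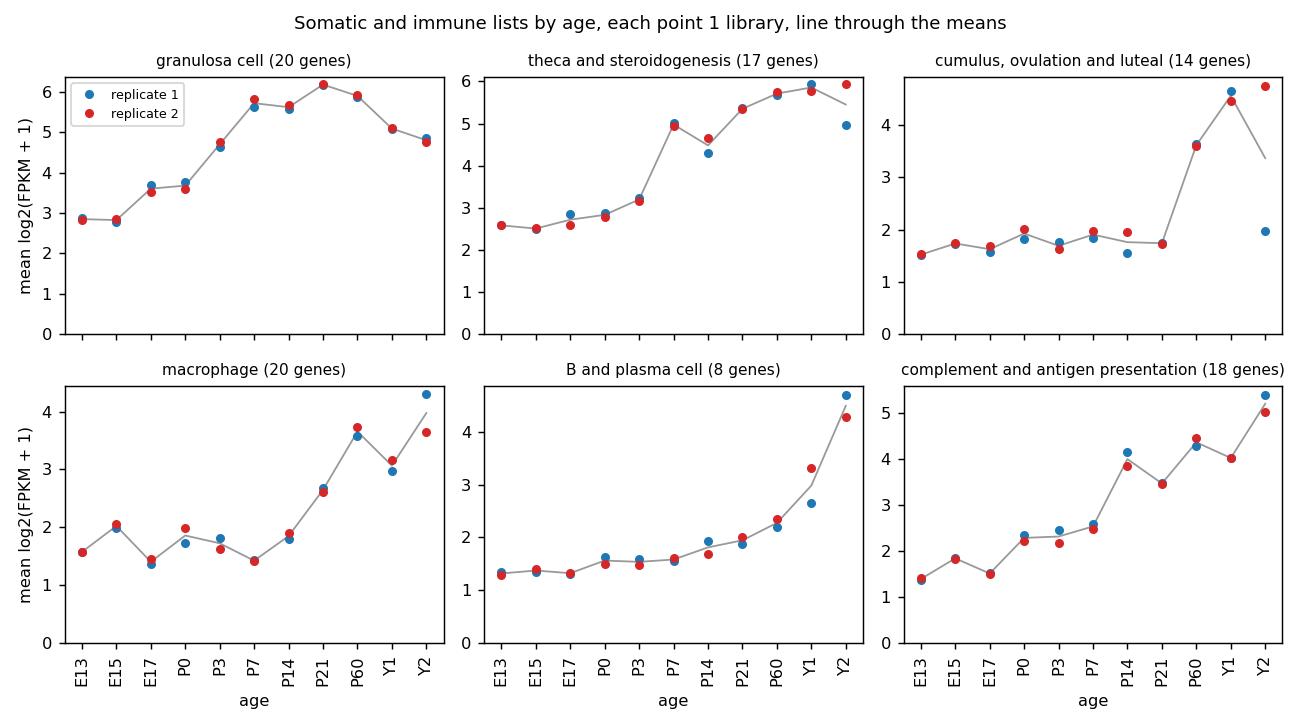
Mean log2(FPKM + 1) of 6 somatic and immune lists (vertical axes) at each of the 11 ages (horizontal axes), with 1 point per library, blue for replicate 1 and red for replicate 2, and a line through the means. The Y2 libraries part in the cumulus, ovulation and luteal list, at 1.98 and 4.76.

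Between P7 and P60, the interval of puberty, macrophage and complement genes rose and oocyte and cell cycle genes fell, while steroidogenic genes went both ways. Of the 15 list calls in this comparison 4 were kept with an estimated correlation, among them macrophage and complement, and those of the oocyte and cell cycle lists were lost. Sfrp4, a secreted WNT antagonist (ENSMUSG00000021319, chromosome 13, 19623104 to 19632994), rose from 4.85 ± 0.68 to 425 ± 58.7 FPKM, a log2 change of 6.18 (limma, adjusted p = 0.0044). Zp2, another egg coat protein (ENSMUSG00000030911, chromosome 7, 120126772 to 120145291), fell from 548 ± 20.7 to 43.8 ± 0.353 FPKM, a log2 change of -3.61 (limma, adjusted p = 5.99e-06). In all, 2151 genes were higher at P60 and 3509 lower, 743 and 847 of them by at least 1 on the log2 scale. Higher genes made up 38% of these calls on the deposited scale, 47.4% under median-of-ratios scaling and 46.5% after quantile normalization.

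All 31 growing oocyte genes fell, also adjusted over the list alone, by a mean of -2.15 on the log2 scale (camera, adjusted p = 1.01e-15; adjusted p = 0.191 with an estimated correlation). Padi6 fell from 522 ± 27.4 to 43.2 ± 6.21 FPKM (log2 -3.57) and Zp3 from 342 ± 0.397 to 35.9 ± 4.09 (log2 -3.22). Mitotic cell cycle genes fell in 25 of 26 cases with none higher, also adjusted over the list alone (camera, adjusted p = 5.49e-11; adjusted p = 0.141 with an estimated correlation). Birc5 fell from 23.2 ± 1.07 to 7.82 ± 1.11 FPKM (log2 -1.46). Ttk fell from 8.01 ± 0.673 to 2.68 ± 0.299 (log2 -1.29) and Cdk1, the mitotic kinase, from 14.9 ± 0.296 to 5.76 ± 0.918 (log2 -1.24).

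Granulosa genes changed within the list, with 8 of 20 higher and 5 lower, or 8 and 6 adjusted over the list alone (camera, adjusted p = 0.193). Inhba, the activin and inhibin beta A subunit, rose from 22.1 ± 11.8 to 255 ± 25.2 FPKM (log2 3.56) and the aromatase gene Cyp19a1 from 9.11 ± 4.1 to 37.9 ± 1.62 (log2 2.01). Kitl, the ligand of the oocyte's KIT receptor, fell from 42.7 ± 7.05 to 4.41 ± 0.653 (log2 -3.01). Of 17 theca and steroidogenesis genes 7 rose and 5 fell, or 8 and 5 adjusted over the list alone (camera, adjusted p = 0.127). Cyp11a1 rose from 46.8 ± 4.37 to 649 ± 39.9 FPKM (log2 3.77). The luteinizing hormone receptor Lhcgr rose from 25.8 ± 5.38 to 151 ± 20.8 (log2 2.52) and Fdx1, the mitochondrial electron donor of CYP11A1, from 80.1 ± 0.758 to 329 ± 31.7 (log2 2.02).

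Of 14 cumulus, ovulation and luteal genes 6 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.0133; adjusted p = 0.51 with an estimated correlation). Ptgfr, the prostaglandin F receptor, rose from 0.264 ± 0.0465 to 36.5 ± 5.25 FPKM (log2 4.88) and Akr1c18, which inactivates progesterone, from 3.42 ± 1.96 to 94.0 ± 13.3 (log2 4.49). Of 20 cholesterol synthesis and uptake genes 1 rose and none fell, also adjusted over the list alone (camera, adjusted p = 0.135). Further large increases were S100a4 (2.21 ± 1.53 to 153 ± 28.2 FPKM, log2 5.66) and Wnt10b (0.0194 ± 0.0275 to 40.8 ± 5.66, log2 5.35). Saa3, an acute phase protein, was listed at 0 in both P7 libraries and at 124 and 79.8 FPKM at P60, and differed between the Y2 libraries, at 6.09 and 84.6.

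Of 20 macrophage genes 18 rose and none fell (camera, adjusted p = 8.9e-17; adjusted p = 0.04 with an estimated correlation), and of 18 complement and antigen presentation genes 16, or 17 adjusted over the list alone (camera, adjusted p = 2.22e-13; adjusted p = 0.04 with an estimated correlation). T and NK cell genes rose in 12 of 13 cases (camera, adjusted p = 1.06e-06; adjusted p = 0.07 with an estimated correlation) and interferon response genes in 14 of 18, or 15 adjusted over the list alone (camera, adjusted p = 5.14e-09; adjusted p = 0.235 with an estimated correlation). Of 12 adipocyte genes 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (camera, adjusted p = 0.208). Adipoq, a fat cell hormone, was listed at 0 in both P60 libraries against 18.5 and 12.8 FPKM at P7 and 13.5 and 70.7 at P14, and Car3 fell from 60.2 ± 13.4 to 3.3 ± 1.41 FPKM (log2 -3.85).

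The senescence list rose from P7 to P60 in 8 of 12 members with 3 lower (camera, adjusted p = 0.00297; adjusted p = 0.04 with an estimated correlation), and heat shock and immediate early genes rose in 11 of 15 (camera, adjusted p = 1.71e-08; adjusted p = 0.04 with an estimated correlation). Germ cell lists fell, with 17 of 32 meiotic genes lower (camera, adjusted p = 1.26e-05; adjusted p = 0.0568 with an estimated correlation), 14 of 15 piRNA genes (camera, adjusted p = 1.28e-10; adjusted p = 0.07 with an estimated correlation) and 7 of 11 oocyte transcription factors with 1 higher (camera, adjusted p = 0.000232; adjusted p = 0.132 with an estimated correlation). These counts were the same adjusted over each list alone. Collagen and matrix genes fell in 13 of 22 cases with 1 higher, or 15 and 1 adjusted over the list alone (camera, adjusted p = 0.00749; adjusted p = 0.359 with an estimated correlation).

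With 1 library of P7 or P60 left out, the calls of Car3 (4 of 4 times, adjusted p up to 0.109), Adipoq (3 of 4, up to 0.0644), Cyp19a1 (3 of 4, up to 0.136) and Lhcgr (2 of 4, up to 0.0833) were lost, as were those of Akr1c18 without P7 replicate 1 (0.0541) and Ptgfr without P60 replicate 1 (0.0503). Hist1h2al, listed at 0 in both P7 libraries and at 35.3 and 40.6 FPKM at P60, and Rpl26, which fell from 42.4 ± 12.5 to 0.815 ± 0.116 FPKM (log2 -4.55), are uncertain, with 81.9% and 27.1% of their words in other transcripts.

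At 2 years, compared with P60, immunoglobulin transcripts rose most, while most oocyte, granulosa, cell cycle and collagen genes fell. Of the 13 list calls in this comparison 0 were kept with an estimated correlation. Ighg2c, an antibody heavy chain constant region (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932), rose from 0.232 ± 0.196 to 267 ± 134 FPKM, a log2 change of 7.68 (limma, adjusted p = 1.31e-11). Cyp17a1 (ENSMUSG00000003555, chromosome 19, 46667165 to 46673172) fell from 240 ± 33.3 to 4.06 ± 0.195 FPKM, a log2 change of -5.57 (limma, adjusted p = 4.78e-10). In all, 1737 genes were higher at Y2 and 2811 lower, 557 and 632 of them by at least 1 on the log2 scale. Higher genes made up 38.2% of these calls on the deposited scale and 44.9% under median-of-ratios scaling. With library quality weights the calls named below for Cd3g, Gzmb, Tnfaip6, Ptx3, Ndufb8 and Sdhc were lost. Also lost were those for Srd5a1, Ctss, Trbc2, Ifi27l2a, Cycs and Mki67 (limma, adjusted p of 0.0686 to 0.445 over all of these). Without P60 replicate 1 the counts were 1060 and 1806, and a fit to P60 and Y2 alone called 318 genes and lost 24 of the calls named for this comparison.

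Of 8 B and plasma cell genes 6 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.000124; adjusted p = 0.197 with an estimated correlation). Igkc rose from 12.3 ± 1.45 to 1540 ± 647 FPKM (log2 6.79). Jchain rose from 0.793 ± 0.262 to 64.8 ± 33.4 (log2 5.11) and Mzb1 from 0.246 ± 0.254 to 9.48 ± 2.81 (log2 3.06). Igha rose from 1.29 ± 0.244 to 164 ± 80.4 FPKM (log2 6.08). The variable segment Igkv10-96 rose from 0.488 ± 0.256 to 113 ± 55.9 (log2 6.18), and Igkv1-117 was listed at 0 in both P60 libraries and at 50.1 FPKM in the lower of the 2 Y2 libraries. Variable segments resemble each other, with 48.0% and 62.6% of the words of these found elsewhere, so their single levels are uncertain. Of 20 macrophage genes 8 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0026; adjusted p = 0.456 with an estimated correlation). Itgax rose from 2.92 ± 0.415 to 9.88 ± 0.0054 FPKM (log2 1.48) and Ctss from 84.3 ± 31.5 to 193 ± 94.4 (log2 1.14). The scavenger receptor Msr1 fell from 9.75 ± 1.6 to 2.41 ± 0.697 (log2 -1.66).

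Of 13 T and NK cell genes 7 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0185; adjusted p = 0.426 with an estimated correlation). Cd3g, of the T cell receptor complex, rose from 1.61 ± 0.0701 to 6.31 ± 2.94 FPKM (log2 1.42) and Trbc2 from 2.44 ± 0.973 to 6.13 ± 3.56 (log2 0.99). The killer cell protease Gzmb fell from 1.97 ± 0.752 to 0.387 ± 0.342 (log2 -1.09). Of 18 complement and antigen presentation genes 8 rose and none fell, with 10 adjusted over the list alone (camera, adjusted p = 2.54e-06; adjusted p = 0.197 with an estimated correlation). H2-Eb1, a class II chain, rose from 38.3 ± 12.4 to 148 ± 41.5 FPKM (log2 1.93). H2-K1, a class I chain, rose from 15.7 ± 1.28 to 60.3 ± 2.79 (log2 1.87) and C4b from 3.28 ± 0.356 to 26.4 ± 14.2 (log2 2.57). H2-K1, C4b and Trbc2 share 22.8%, 48.3% and 48.5% of their words with other transcripts and are uncertain. Of 18 interferon response genes 1 fell, Ifi27l2a from 65.5 ± 1.98 to 34.0 ± 4.63 FPKM (log2 -0.93), and none did adjusted over the list alone (camera, adjusted p = 0.826).

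Of 31 growing oocyte genes 28 fell and none rose, with 29 adjusted over the list alone (camera, adjusted p = 9.97e-12; adjusted p = 0.313 with an estimated correlation). The list means were 3.17 and 3.07 in the P60 libraries and 2.22 and 1.06 in the Y2 libraries, so the size of the fall depends on the library. Zp2 fell from 43.8 ± 0.353 to 8.7 ± 7.98 FPKM (log2 -2.51). Ooep fell from 12.4 ± 1.63 to 1.76 ± 1.74 (log2 -2.44) and Zp3 from 35.9 ± 4.09 to 7.9 ± 7.78 (log2 -2.39). Of 20 granulosa genes 12 fell and 2 rose, or 13 and 2 adjusted over the list alone (camera, adjusted p = 3.08e-05; adjusted p = 0.179 with an estimated correlation). Inhba fell from 255 ± 25.2 to 23.8 ± 16.0 FPKM (log2 -3.53) and Slc18a2 from 98.9 ± 18.8 to 14.2 ± 10.5 (log2 -2.90). Kitl rose from 4.41 ± 0.653 to 34.3 ± 11.5 (log2 2.67). Mitotic cell cycle genes fell in 24 of 26 cases, also adjusted over the list alone (camera, adjusted p = 1.03e-14; adjusted p = 0.197 with an estimated correlation). Mki67 fell from 18.2 ± 2.21 to 4.99 ± 0.436 FPKM (log2 -1.68), a call lost with library quality weights (limma, adjusted p = 0.0795). Top2a fell from 15.1 ± 1.57 to 4.29 ± 0.189 (log2 -1.61) and Kif20a from 7.72 ± 0.192 to 1.99 ± 0.439 (log2 -1.55).

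Of 22 collagen and matrix genes 15 fell and none rose, with 18 adjusted over the list alone (camera, adjusted p = 8.18e-11; adjusted p = 0.179 with an estimated correlation). Col1a1 fell from 145 ± 1.16 to 23.6 ± 4.29 FPKM (log2 -2.58). Col3a1 fell from 230 ± 18.9 to 42.7 ± 3.83 (log2 -2.40) and Col1a2 from 103 ± 2.71 to 24.3 ± 2.61 (log2 -2.05). Of 17 theca and steroidogenesis genes 2 rose and 4 fell, or 3 and 5 adjusted over the list alone (camera, adjusted p = 0.924), with a median of 0.19 and a mean of -0.25. The Y2 libraries pulled this mean in opposite directions, with list means of 4.97 and 5.93 against 5.67 and 5.75 at P60. Beside Cyp17a1, Insl3, a theca cell hormone, fell from 14.9 ± 2.49 to 1.21 ± 0.311 FPKM (log2 -2.84), and Srd5a1 rose from 7.38 ± 0.186 to 16.0 ± 7.51 (log2 0.95). Of 12 senescence genes 3 rose and 6 fell, or 3 and 8 adjusted over the list alone (camera, adjusted p = 0.291). The chemokines Ccl2 (18.6 ± 7.58 to 1.41 ± 0.116 FPKM, log2 -2.97) and Cxcl1 (8.42 ± 2.91 to 2.05 ± 1.5, log2 -1.68) fell, and Igfbp3 rose from 3.65 ± 0.245 to 15.5 ± 9.72 (log2 1.70). Of 25 oxidative phosphorylation genes 2 rose and 2 fell, or 2 and 1 adjusted over the list alone (camera, adjusted p = 0.433). Sdhc rose from 17.4 ± 0.547 to 23.2 ± 2.1 FPKM (log2 0.39). Ndufb8 fell from 13.3 ± 0.99 to 9.01 ± 0.126 (log2 -0.51) and Cycs, with 29.4% of its words elsewhere, from 1.85 ± 0.246 to 1.18 ± 0.242 (log2 -0.39).

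Surface epithelium genes rose between P60 and Y2 in 10 of 13 cases, or 11 adjusted over the list alone (camera, adjusted p = 3.59e-06; adjusted p = 0.313 with an estimated correlation), with list means of 4.51 and 3.39 in the Y2 libraries. Endothelial genes rose in 11 of 14, also adjusted over the list alone (camera, adjusted p = 2.21e-05; adjusted p = 0.197 with an estimated correlation). Oviduct and mesonephric duct genes rose in 4 of 12, or 5 adjusted over the list alone (camera, adjusted p = 0.0193; adjusted p = 0.197 with an estimated correlation). Of 5 adrenal cortex genes none passed the threshold (camera, adjusted p = 0.805), with list means of 3.3 and 3.33 at P60 and 2.91 and 3.69 at Y2. Testis somatic cell genes were higher in 1 of 12 and lower in 4, also adjusted over the list alone (camera, adjusted p = 0.356). Cholesterol synthesis and uptake genes rose in 2 of 20, or 0 adjusted over the list alone (camera, adjusted p = 0.00374; adjusted p = 0.723 with an estimated correlation). This rise rests on Y2 replicate 2: the list means were 3.86 and 3.84 in the P60 libraries and 3.21 and 6.37 in the Y2 libraries, and without Y2 replicate 2 the mean change was -0.63 in place of 0.94. Without Y2 replicate 1 the list calls for macrophage, T and NK cell and oviduct genes were lost (camera, adjusted p of 0.167, 0.061 and 0.0725).

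The 2 Y2 libraries parted in luteal and cholesterol genes. Star, which carries cholesterol into mitochondria, was at 123 and 3270 FPKM, Akr1c18 at 2.97 and 219, Sfrp4 at 10.9 and 2220, Ptgfr at 0.432 and 164, and Hsd17b7, of cholesterol and estradiol synthesis and chosen after its values were seen, at 5.62 and 1440. Of 14 cumulus, ovulation and luteal genes 2 fell, Tnfaip6 (1.77 ± 0.632 to 0.372 ± 0.0148 FPKM, log2 -0.99) and Ptx3 (1.69 ± 0.0655 to 0.812 ± 0.298, log2 -0.58), also adjusted over the list alone (camera, adjusted p = 0.805). Against P60, 989 genes were higher and 1760 lower with both Y2 libraries and with each alone, and 287 were called in opposite directions with the 2 libraries. Calls for Cycs (3 of 4 times, adjusted p up to 0.228), Ifi27l2a (3 of 4, up to 0.107), Trbc2 (2 of 4, up to 0.171) and Ctss (2 of 4, up to 0.142) were lost on leaving out 1 library, and that for Srd5a1 without Y2 replicate 1 (0.0542). Cwc22, a splicing factor (166 ± 10.7 to 4.05 ± 0.488 FPKM, log2 -5.05), Serpina3a (28.9 ± 1.64 to 0.461 ± 0.249, log2 -4.36) and Ifi202b (21.5 ± 3.63 to 0.0931 ± 0.0171, log2 -4.35) were among the largest decreases. Cwc22 has 22.8% of its words in other transcripts and is uncertain. At P0 Cwc22 was at 5.74 and 4.01 FPKM and Serpina3a at 1.48 and 1.44. At P14 Cwc22 was at 99.8 and 6.24 FPKM and Serpina3a at 0.249 and 0.229. Neither gene followed the order of the ages, so whether their falls at Y2 belong to ageing is uncertain. Hist1h2al was at 35.3 and 40.6 FPKM at P60 and listed at 0 in both Y2 libraries, with the same uncertainty as above.

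**Figure D3:**
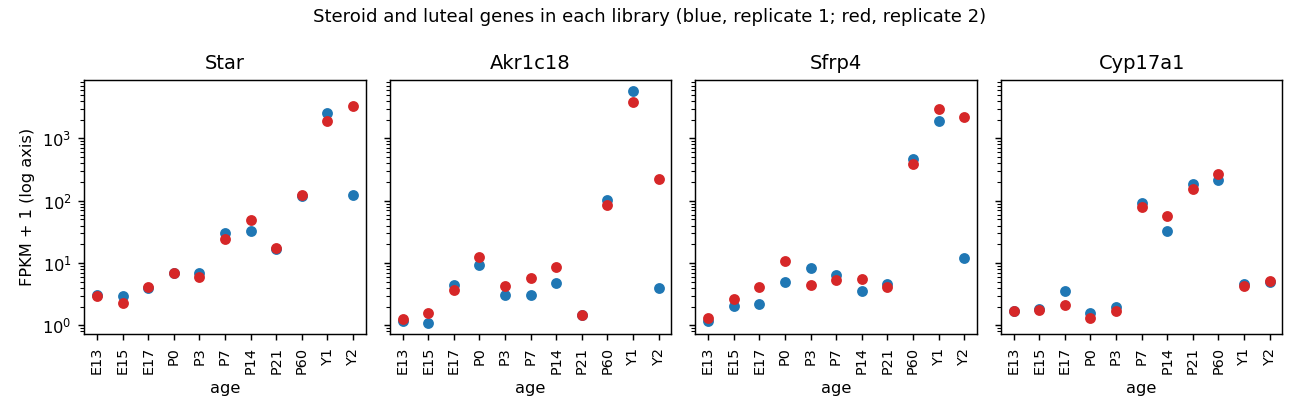
FPKM + 1 on a log axis (vertical) of Star, Akr1c18, Sfrp4 and Cyp17a1 in each of the 22 libraries by age (horizontal), blue for replicate 1 and red for replicate 2. Star lies at 2560 and 1910 FPKM at Y1 and at 123 and 3270 at Y2, and Cyp17a1 at 217 and 264 at P60 against 3.93 and 4.2 at Y2.

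In the fit to all 11 ages, the most genes changed from E15 to E17 (3037 higher, 2508 lower) and the fewest from P7 to P14 (399 and 197). With only the 2 ages of a step in the fit, the count was highest from P14 to P21, 3931 against 3522 from E15 to E17. From E13 to E15, 1925 genes rose and 1987 fell, with Dppa3, a germ cell factor, falling from 42.3 ± 0.536 to 1.39 ± 0.906 FPKM (log2 -4.23). Zcchc5 (0.782 ± 0.311 to 23.6 ± 0.615 FPKM, log2 3.80) and Dpt (1.24 ± 0.456 to 16.1 ± 4.15, log2 2.93) rose. Dppa3 has 29.6% of its words in other transcripts and is uncertain. The count of 3912 changed genes was 1711 without E15 replicate 2. From E15 to E17, Sohlh1 rose from 1.33 ± 0.346 to 85.5 ± 21 (log2 5.20), Hbb-y fell from 214 ± 11.3 to 2.06 ± 0.7 (log2 -6.15), and Thy1 from 33.7 ± 0.344 to 0.808 ± 0.359 (log2 -4.28). From E17 to P0, 1266 genes rose and 1436 fell, among them Padi6 (1.39 ± 0.195 to 26.3 ± 8.83, log2 3.48) and Stfa1 (2.93 ± 2.85 to 38.7 ± 2.18, log2 3.55) upward, and Cwc22 (65.1 ± 1.94 to 4.88 ± 1.22, log2 -3.51) and Pet117 (13.1 ± 1.57 to 0.0903 ± 0.00532, log2 -3.69) downward. Stfa1, with 43.8% of its words elsewhere, and Cwc22 are uncertain. That count of 2702 was 1619 without E17 replicate 2, and limma on these 2 ages alone called 0 genes, with 4082 at an unadjusted p under 0.05. Pet117 lost its call with any 1 of the 4 libraries left out (adjusted p up to 0.0902).

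From P0 to P3, 1940 genes rose and 1803 fell. Nlrp14 rose from 4.87 ± 1.37 to 198 ± 16.0 FPKM (log2 5.10), and the pseudogene Rps2-ps10, with 97.2% of its words elsewhere, from 2.58 ± 0.351 to 105 ± 0.311 (log2 4.89). The P0 libraries differed in erythroid transcripts, with list means of 3.34 and 5.65. Hba-a2 fell from 282 ± 299 to 0.0629 ± 0.0889 (log2 -7.47) and Rpl29 from 153 ± 15.2 to 0.901 ± 0.264 (log2 -6.34). The 3743 changed genes came to 2339 without P3 replicate 2. From P3 to P7, 1265 rose and 1447 fell, or 1584 in all in place of 2712 without P7 replicate 1. Cyp17a1 rose from 0.839 ± 0.18 to 84.0 ± 8.4 (log2 5.53) and Car3 from 0.833 ± 0.5 to 60.2 ± 13.4 (log2 5.07). Rps2-ps10 (105 ± 0.311 to 1.93 ± 0.0214, log2 -5.18) and Pet117 (18.9 ± 2.9 to 0.0884 ± 0.00336, log2 -4.18) fell. Both Pet117 and Car3 also differed over 4-fold between replicates of single ages, Pet117 at 14 and 0.0968 FPKM at P21 and 11.2 and 0.0859 at Y2, and Car3 at 75.2 and 2.88 at Y1, so their changes between ages are uncertain. Car3 and Pet117 each lost this call in 2 of 4 leave-outs, at adjusted p of up to 0.0648 and 0.0605.

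At P14 against P7, Iigp1, an interferon-induced GTPase, rose from 1.99 ± 0.313 to 57.8 ± 36.1 FPKM (log2 4.15) and Rpl29 from 0.758 ± 0.00395 to 97.4 ± 34.0 (log2 5.76). The pseudogenes Eif3s6-ps2 (76.1 ± 19.1 to 6.48 ± 1.56, log2 -3.36) and Hmgb1-ps7 (57.7 ± 4.98 to 8.55 ± 0.45, log2 -2.62) fell. These pseudogenes have 41.4% and 77.3% of their words in other transcripts and are uncertain, as is Rpl29. Both pseudogenes are also among the genes, given below, that set P0, P14 and Y2 apart from the other ages. The interferon response list stood at 3.49 and 1.87 in the P14 libraries. Of the 596 calls, 66.9% were higher against 56.7% after quantile normalization, 289 calls were left without P7 replicate 1, and limma on these 2 ages alone called 0, with 2400 at an unadjusted p under 0.05. From P14 to P21, 1462 rose and 2853 fell, 33.9% higher against 50.2% after quantile normalization. The BMP antagonist Grem1 rose from 0.138 ± 0.0646 to 39.5 ± 0.353 (log2 5.15) and Serpina3a from 0.239 ± 0.0138 to 51.4 ± 5.25 (log2 5.40). Rpl29 fell from 97.4 ± 34.0 to 0.811 ± 0.135 (log2 -5.72). Serpina3a is among the genes that set P0, P14 and Y2 apart as well, so its change with age is uncertain. Cfd, a fat cell protease, fell from 178 ± 194 to 6.63 ± 9.06 (log2 -4.80), a call lost in 2 of 4 leave-outs (adjusted p up to 0.292), while the adipocyte list stood at 2.83 and 4.73 at P14. The count of 4315 was 2677 without P21 replicate 1.

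From P21 to P60, 1099 genes rose and 1080 fell, with Sfrp4 (3.4 ± 0.425 to 425 ± 58.7 FPKM, log2 6.59) and Saa3 (0.624 ± 0.704 to 102 ± 31.1, log2 6.02) upward and Rpl26 (59.8 ± 9.93 to 0.815 ± 0.116, log2 -5.06) downward. Olfr1033 was at 14.7 and 10.5 FPKM at P21 and listed at 0 in both P60 libraries. The total of 2179 was 1163 without P21 replicate 2, and Sfrp4 lost its call in 2 of 4 leave-outs (adjusted p up to 0.0548). From P60 to Y1, 718 rose and 1608 fell, 30.9% higher against 46.7% under median-of-ratios scaling and 45.9% after quantile normalization. Akr1c18 rose from 94.0 ± 13.3 to 4770 ± 1300 (log2 5.63) and Star from 120 ± 4.34 to 2240 ± 459 (log2 4.19). Cyp17a1 fell from 240 ± 33.3 to 3.41 ± 0.243 (log2 -5.77) and H2-Eb1 from 38.3 ± 12.4 to 1.58 ± 0.0266 (log2 -3.89). The total of 2326 was 977 without Y1 replicate 1, where the call of Star was lost too (limma, adjusted p = 0.0604). From Y1 to Y2, 1946 rose and 1575 fell, 55.3% higher against 45.0% after quantile normalization, and the total of 3521 ranged from 2200 without Y1 replicate 1 to 5340 without Y2 replicate 2. Ighg2c rose from 0.983 ± 0.143 to 267 ± 134 (log2 6.98) and Rpl29 from 0.376 ± 0.024 to 110 ± 25.2 (log2 6.32), while Akr1c18 fell from 4770 ± 1300 to 111 ± 153 (log2 -7.31). Hist1h2al was at 83.7 and 101 FPKM at Y1 and listed at 0 in both Y2 libraries. In a fit to Y1 and Y2 alone, 68 genes were called.

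**Figure D4:**
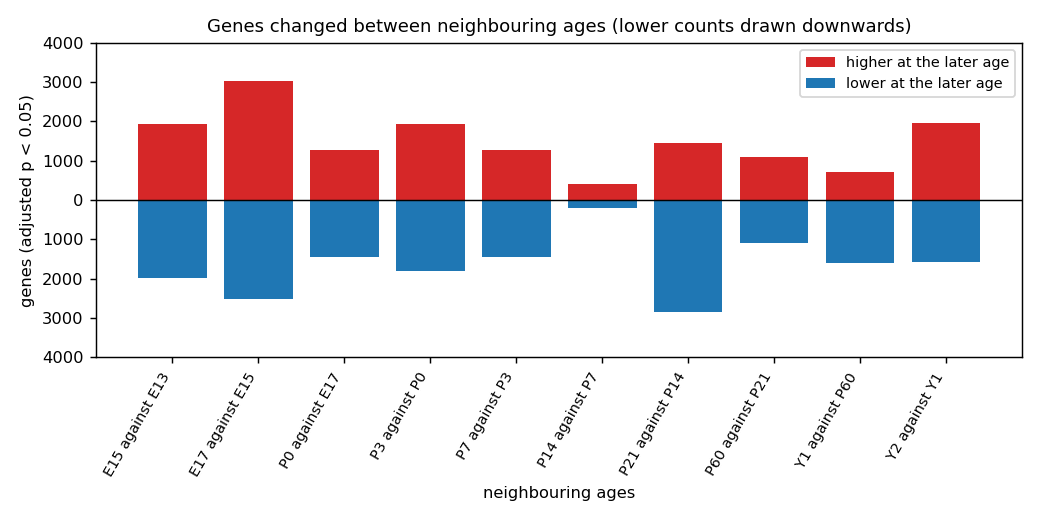
Number of genes changed at adjusted p under 0.05 (vertical axis) in each of the 10 steps between neighbouring ages (horizontal axis), with genes higher at the later age drawn upward in red and genes lower drawn downward in blue. The upward bar is tallest from E15 to E17, at 3037, and the downward bar from P14 to P21, at 2853. Both are shortest from P7 to P14, at 399 and 197.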

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

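Of the settings here, library quality weights and the fits leaving out Y2, P0 with P14, or all 3 of these ages were chosen after the data had been seen. Settings that need read counts were not run, since the values are FPKM. Of 2345 recomputed gene results 2250 kept their call, 95 lost it and none reversed. Of 1756 list results 1654 had the same outcome, which counts lists called in neither fit, 45 lost their call and 55 gained one. Of the 45 losses, 39 came with the estimated correlation. In 2, of the luteal and cholesterol lists given below, camera's direction turned with the list called in at least 1 of the fits compared. Turns of lists called in neither fit were not counted. With 1 library left out, the lone library of its age is assumed to vary like the others. The cause of the shifts was not tested.

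With a filter at 5 FPKM, 1109 genes were higher at Y2 than at P60 and 368 changed from P7 to P14. With library quality weights the Y2 to P60 counts were 615 higher and 968 lower, and the step counts were 6080 (E13 to E15), 4256 (P3 to P7), 4921 (P21 to P60), 4731 (P60 to Y1) and 1052 (Y1 to Y2). Calls lost with these weights for Y2 against P60 included Mki67 (limma, adjusted p = 0.0795), Cd3g (0.0695), Tnfaip6 (0.219), Ptx3 (0.172), Gzmb (0.128), Ndufb8 (0.174) and Sdhc (0.166). Also lost were Srd5a1 (limma, adjusted p = 0.0686), Ctss (0.184), Trbc2 (0.181), Ifi27l2a (0.438) and Cycs (0.445). Leaving P0, P14 and Y2 out of the fit gave 4148 (P3 to P7), 3671 (P21 to P60) and 4182 (P60 to Y1). Leaving out Y2 gave 1101 (P7 to P14), 3368 (P21 to P60) and 3862 (P60 to Y1). With only the 2 compared ages in the fit, Y2 against P60 had 132 higher and 186 lower, and the steps 3522 (E15 to E17), 0 (E17 to P0), 2397 (P0 to P3), 0 (P7 to P14) and 68 (Y1 to Y2).

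Leaving out 1 library at a time gave, for E17 against E13, 1981 to 2572 higher and 1459 to 1914 lower, and for Y2 against P60, 1060 to 2383 higher and 1806 to 3928 lower. Changed genes per step were 1711 to 3020 (E13 to E15), 1619 to 1804 (E17 to P0), 2339 to 2770 (P0 to P3), 1584 to 1859 (P3 to P7), 289 to 486 (P7 to P14), 2677 to 3383 (P14 to P21), 1163 to 1242 (P21 to P60), 977 to 1433 (P60 to Y1) and 2200 to 5340 (Y1 to Y2). For Y2 against P60 the mean log2 change of the luteal list lay between -1.64 and 1.14, against -0.25 with all libraries, and that of the cholesterol list between -0.63 and 2.52, against 0.94.

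A replicate block changed none of the calls compared for 161 gene results and 112 list results. Counts over all genes shifted by less than 1.5 times, to 14123 in the F test, 1693 higher and 2766 lower at Y2 than at P60, and 2174 from P60 to Y1. The replicate numbers do not pair libraries across ages: over 55 pairs of ages the correlation of replicate differences lay between -0.13 and 0.26, with a median of 0.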

Other observations

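All tests below were chosen after the patterns had been seen, except the 2 that take gene copies as the cause for all genes of a pattern. Age is the only labelled factor of the design, and reproductive state cannot be told apart from it between P60, Y1 and Y2. Apart from adrenal tissue in a library, no biological explanation was tested.

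Some list members were chosen after their values were seen. From P7 to P60 Cd68, of macrophages, rose from 2.5 ± 0.597 to 25.3 ± 1.29 FPKM (log2 2.92), and Cd74, of antigen presentation, from 3.36 ± 0.263 to 139 ± 71.5 (log2 4.91). Upk1b, of the surface epithelium, rose from 1.34 ± 0.313 at P60 to 34.1 ± 12.7 at Y2 (log2 3.87).

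The Y2 libraries differ in luteal and cholesterol synthesis genes, which could come from animals with and without active luteal tissue, though nothing here tests that. Library depth is not favoured as the cause, since over genes at 10 FPKM or more the SD between the replicates was 0.538 against 0.108 to 0.24 at the other ages. A library of another age of this series under the Y2 label is not favoured, because the pair had r = 0.94 against best values of 0.91 and 0.929 with other ages. Adrenal tissue is also not favoured, with Cyp11b1, Cyp11b2 and Cyp21a1 summing to 0.0188 FPKM where Star was at 3270.

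A set of 19 genes, 8 higher and 11 lower, sets P0, P14 and Y2 apart from the 8 other ages, the most among 84 sets of 3 ages without neighbours, where the next had 14. Serpina3a, Eif3s6-ps2 and Hmgb1-ps7, named above, are among the 19. Annotated gene copies do not account for all of them at the limit used, as 6 of 18 had at least 50% of their words elsewhere and 2 had none. Copies missing from the annotation were not searched, so shared reads are not excluded as the cause for all. Reads shared with annotated copies may be the cause for part, since that share was 33.3% against 3.3% of background genes (Fisher exact test, two-sided p = 2.92e-05). Genetic differences between the animals are left open. Of 4 genes known to vary between strains, 3 (Cwc22, Ifi202b and H2-Ea-ps), none of them among the 19, were lower in both Y2 libraries than in every P60 and Y1 library. Cwc22 and Ifi202b had already been seen to fall at Y2 and the count does not cover P0 or P14, so it tests nothing. At P0 Cwc22 was at 5.74 and 4.01 FPKM, with Ifi202b and H2-Ea-ps at 0 in both libraries. The P14 libraries split in Cwc22, at 99.8 and 6.24. There Ifi202b was at 3.63 and 1.81 and H2-Ea-ps at 0.909 and 0.279, so these genes did not set P14 apart as they did Y2. Trim12a, outside that count, was at 1.98 to 6.6 FPKM at P0, P14 and Y2, and also at 1.29 to 2.53 at E17, P3 and P21.

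Without a floor of 10 FPKM, 58 genes had a 4-fold difference between replicates at 2 or more ages, among them 6 adipocyte and 3 erythroid list members. Overlapping exons do not account for them as a whole, with 23 of 58 (39.7%) overlapping another gene against 35.2% of the rest (Fisher exact test, p = 0.493). Annotated gene copies do not account for all at that limit, with 8 of 50 past it and 14 without any shared word. Copies missing from the annotation were again not searched. Copies may be the cause for part, at 16.0% against 3.3% (Fisher exact test, two-sided p = 0.000445).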
